A study of Oryza sativa with 46 samples.

How the data were processed

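RNA was sequenced from the roots of rice seedlings (Oryza sativa ssp. japonica, cultivar Kitaake), in 46 libraries of 16 groups. Per the labels' protocols, seedlings grew in hydroponics with 14 h of light (120 µmol of photons per square metre and second, 27 °C) and 10 h of dark (23 °C) at 70% relative humidity. Acclimated plants spent 12 h at 15 °C from the start of a night (letter A). Cold lasted 24 h and reached the whole plant at 5 °C (C), the roots alone (C-R, medium at 5 °C and air at 20 °C) or the leaves alone (C-L, air at 5 °C and medium at 20 °C). The split treatments used thermoregulated vessels with new medium, whereas the untreated plants (S) were not kept in those vessels or at 20 °C. The suffix 1 marks roots taken directly after cold at 14 days, 2 marks roots after 3 further days of recovery at 17 days, and 0 marks plants before cold. The labels give 12 days for S0 and the protocol 13. Roots were collected 2 h after dawn, and RNA came from a spin-column kit for plant tissue. The series design speaks of 3 independent biological replicates, and replicates of a group were treated as separate samples. S1 holds 1 library and each other group 3.

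The deposited values were estimated counts, TPM and effective lengths per transcript, as Salmon writes them per the file headers. Per the submitters' processing notes the reads were trimmed with Trimmomatic and quantified with Salmon 1.3.0. The Trimmomatic version, the Salmon settings, the transcript set and its genome build are not given in the sources used here. The deposited estimated counts of 66183 transcripts were summed to 55860 loci by the locus part of the transcript name and rounded to whole numbers, which changed a library total by at most 0.000596%. The authors' TPM values were used only for length-scaled counts as an alternative, and the deposited effective lengths (in bases) for a description of the libraries. Salmon shares reads among similar transcripts, so loci with near-identical copies, such as the tandem DREB1 genes, the plasma membrane aquaporins and the RAB16 genes, are uncertain.

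Depth ranged from 14005648 to 26869818 assigned reads per library, and 25957 to 28072 loci had a read. The 10 most abundant loci took 3.65% to 15.1% of the reads. Molecular identifiers are not given in the sources used here, so counts are of reads and not of molecules. Over the 45 pairs of replicates, the chi-square per degree of freedom of the counts was 5.20 to 166 (median 49.2), and 0 pairs held identical values.

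Loci were kept with edgeR's filterByExpr (minimum count 10, minimum total 15, smallest group of 1 library), which left 26120. One model with 16 group means was fitted to all 46 libraries with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, R 4.3.3), and Benjamini-Hochberg adjusted p-values under 0.05 count as passing. Adjusted p-values of loci are from this test unless DESeq2 is named. Fold changes are log2 values with their standard error, and expression levels are counts scaled to library size (CPM) with the SD over libraries. In comparisons with S1 the spread comes from the other groups, so the single S1 library is assumed to vary like them, as is a group with 1 library within a class. The comparisons were acclimation alone (A0 and S0), each cold treatment with S1, the cold treatments with one another, acclimated with unacclimated plants for each treatment, and the same after recovery, with an interaction test at each time of whether the acclimation difference varied among the 3 cold targets.

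Gene lists were written from memory, as symbol and locus pairs, before the data were examined, as were the comparisons, tests and most alternatives. Of 213 loci in 19 lists, 154 were supported by a RefSeq gene table of assembly ASM3414082v1. That table was not matched on the deposited locus identifiers, so support means that the symbol lay on the chromosome the locus identifier gives, in the same order along it. For 55 loci the symbol was not in that table, and they stay in the list tests without being named. They include every shoot photosynthesis marker but the rubisco activase RCA. For 4 loci the table contradicted the symbol, and these were dropped. Lists were tested against all other loci with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 19 lists of a comparison. Correlations estimated from the data were the alternative: of 304 list tests, 102 passed with the preset and 7 with the estimated correlation. The 7 were heat shock proteins in A0 and S0, dehydrins in C1 and C-R1 with S1, in C-L1 with C-R1 and in AC1 with C1, and shoot photosynthesis markers in C-L1 with S1 and in AC-L2 with C-L2. The markers of other tissues were photosynthesis genes for shoot, cellulose synthases for xylem and 4 genes for root zones. The dehydrin list also holds other osmoprotection genes, and dehydrins alone were not tested. The rule for named genes, set at the same time, allowed any member of these lists. It also allowed, per comparison, the 8 rising and 8 falling loci with the largest change among those that passed, with a mean of at least 5 CPM in the higher group, no overlap between the groups and an informative product name. Product names are not given in the sources used here, so only list members are named and planned keyword lists could not be used.

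Alternatives were DESeq2's size factors in edgeR, no filter on low counts, DESeq2 1.42.0, length-scaled counts, a replicate block, a fit of only the compared groups, 7 untreated libraries as 1 control for S1, and leaving out each library in turn. Alternatives chosen after the data were seen concern library class. Effective lengths split the libraries into 22 with a low and 24 with a high mean difference between length and effective length over transcripts longer than 3000 bases (boundary 100 bases; at most 75.2 and at least 116 bases). This class was used as a model term and for fits within each class.

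The scripts were tested on simulated counts of 25598 loci with 200 changed. At the size of the A0 and S0 comparison edgeR recovered 34% of 2-fold and 83% of 4-fold changes with 9.3% false calls, and DESeq2 40% and 85% with 16.7%. With 3 libraries against 1, as in C1 and S1, edgeR recovered 6% and 54% (3.23% false) and DESeq2 10% and 58% (20.9% false). For the interaction edgeR recovered 5% and 62% with 2.9% false calls. The simulated counts held no library class and no correlation between loci. These shares of false calls may therefore not hold for the real libraries.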

Results

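The series followed root transcripts of rice seedlings through a night of acclimation at 15 °C, 24 h of cold aimed at the whole plant, the roots or the leaves, and 3 days of recovery. The 46 libraries held 14005648 to 26869818 assigned reads. Cold roots separated from all others on the first principal component, which held 45.9% of the variance: C1, AC1, C-R1 and AC-R1 libraries lay between 152 and 185, with AC-R1 replicate 1 at 83.3, whereas the single S1 library lay at -91.1. The second component (13.4%) carried the roots of plants with cold leaves, at 136 to 176 in C-L1 and up to 115 in AC-L1. Recovered roots of all treatments lay with the untreated ones on the first component.

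**Figure D1:**
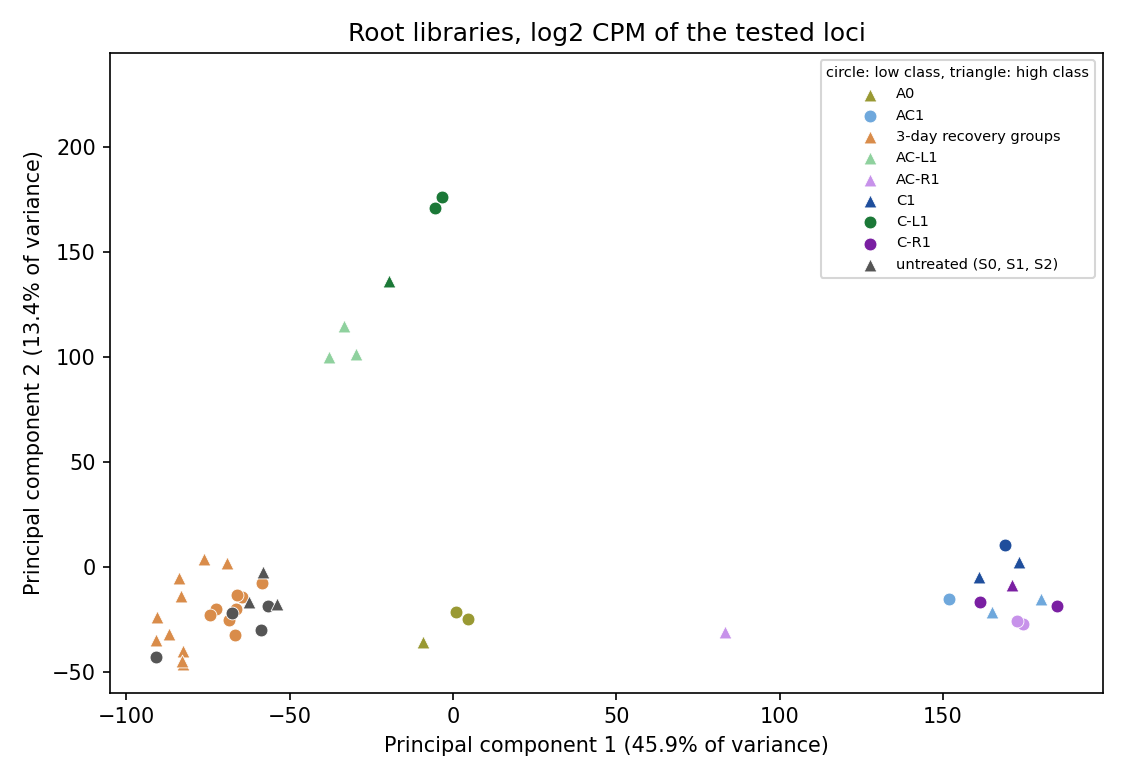
Each point is 1 of the 46 root libraries on the first principal component (45.9% of the variance, x axis) and the second (13.4%, y axis) of log2 CPM, with the treatment by colour. Libraries of cold roots lie at 83.3 or more on the x axis, and those of C-L1 at 136 or more on the y axis, above those of AC-L1 at up to 115.

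Libraries also split into 22 of a low and 24 of a high class by Salmon's effective lengths, and most groups held both classes. Around the group means, the first component (25.4% of the remaining variance) followed the effective length shift over 45 libraries (Pearson r = -0.901, Spearman rho = -0.905, permutation p = 1e-05 each, the smallest the permutations give). Without the 2 libraries farthest from the median shift r was -0.898. A class term passed at 11324 of 26120 loci. Counts of changed genes within each class are therefore given beside the pooled ones.

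Acclimation alone (A0 against S0, n = 3 each) raised 5 of 13 tested abscisic acid genes and lowered 5 of 14 aquaporins, 3 of 4 heat shock genes and an ascorbate peroxidase. Of these lists heat shock passed with an estimated correlation (adjusted p = 0.013), the others not (0.164 and 0.445). NCED3 (LOC_Os03g44380), of abscisic acid synthesis, rose from 0.266 ± 0.197 CPM in S0 to 2.13 ± 0.956 CPM in A0 (mean ± SD; log2 fold change ± SE 3.06 ± 0.62, 2.47 without S0 replicate 3, adjusted p = 0.000994). APX2 (LOC_Os07g49400), a cytosolic ascorbate peroxidase, fell from 1019 ± 97.5 CPM in S0 to 131 ± 4.59 CPM in A0 (adjusted p = 7.56e-11), and the vacuolar aquaporin TIP1;1 (LOC_Os03g05290) fell from 1546 ± 163 CPM in S0 to 323 ± 53.3 CPM in A0 (adjusted p = 7.72e-05). The heat shock factor HSFA2A (LOC_Os03g53340) had 44.4 ± 23.2 CPM and 2497 reads in S0 and 0 reads in the A0 libraries (adjusted p = 1.02e-09).

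In the abscisic acid list 5 of 13 tested members rose and 8 did not pass (5 up adjusted over the list alone). Abscisic acid genes gave a camera adjusted p of 0.00016, and adjusted p = 0.164 with an estimated correlation. Of the 5 PP2C phosphatases of its signalling that were tested, 3 rose, with log2 fold changes (± SE) for PP2C68 (LOC_Os09g15670, 3.18 ± 0.77, 4.66 without S0 replicate 1), PP2C09 (LOC_Os01g62760, 2.32 ± 0.51, 3.05 without S0 replicate 1) and PP2C50 (LOC_Os05g46040, 1.27 ± 0.25) (adjusted p up to 0.00547). Among aquaporins, 5 of 14 tested members fell and 9 did not pass (6 down adjusted over the list alone), among them TIP2;2 (LOC_Os06g22960, -1.79 ± 0.38) and PIP1;2 (LOC_Os04g47220, -1.52 ± 0.36). Aquaporins reached a camera adjusted p of 0.00794, and adjusted p = 0.445 with an estimated correlation. Of heat shock genes, 3 of 4 tested members fell and 1 did not pass (3 down adjusted over the list alone), with HSP18.0 (LOC_Os01g08860, -3.00 ± 0.53, -3.72 without A0 replicate 1) and HSFA2C (LOC_Os10g28340, -2.97 ± 0.26). Heat shock genes had a camera adjusted p of 1.05e-07, and adjusted p = 0.013 with an estimated correlation. In the fermentation list 2 of 5 tested members fell and 3 did not pass (4 down adjusted over the list alone), including the haemoglobin HB1 (LOC_Os03g13140, -2.41 ± 0.50) and the pyruvate decarboxylase PDC2 (LOC_Os03g18220, -0.99 ± 0.24). Fermentation genes gave a camera adjusted p of 0.0153, and adjusted p = 0.179 with an estimated correlation. Clock genes went both ways: 4 of 9 tested members rose, 2 fell and 3 did not pass (4 up and 3 down adjusted over the list alone). Clock genes reached a camera adjusted p of 0.21. The clock genes PRR95 (LOC_Os09g36220, 2.14 ± 0.28) and PRR1 (LOC_Os02g40510, 1.34 ± 0.17) rose and PRR73 (LOC_Os03g17570, -1.46 ± 0.18) fell. The ammonium transporter AMT1;1 (LOC_Os04g43070, 2.07 ± 0.37) and the stress transcription factor NAC5 (LOC_Os11g08210, 1.47 ± 0.34) rose. In the nutrient uptake list 2 of 18 tested members rose and 16 did not pass (2 up adjusted over the list alone). Nutrient uptake genes had a camera adjusted p of 0.0449, and adjusted p = 0.629 with an estimated correlation. In sugar use 1 of 6 tested members rose and 5 did not pass (2 up adjusted over the list alone), and in cell division 2 of 7 tested members fell and 5 did not pass (6 down adjusted over the list alone). Sugar use genes gave a camera adjusted p of 0.0449, and adjusted p = 0.164 with an estimated correlation. Cell division genes reached a camera adjusted p of 0.0062, and adjusted p = 0.445 with an estimated correlation. Across these examples adjusted p was at most 0.00547.

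In all, 3057 of 26120 loci changed, 1319 up and 1738 down, and 462 and 1175 of them by at least 2-fold. Within the low class (2 against 2 libraries) 3508 changed and within the high class (1 against 1) 2648. The count was 2036 without A0 replicate 2 and 1820 without A0 replicate 3.

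Cold on the whole plant (C1, n = 3, against the single S1 library) raised 10 of 13 tested abscisic acid, 10 of 12 jasmonate, 11 of 17 dehydrin and 13 of 20 cold regulator genes in roots and lowered 11 of 14 aquaporins. Of these only the dehydrin list passed with an estimated correlation (adjusted p = 0.04, others 0.0681 to 0.0757). WRKY71 (LOC_Os02g08440), a defence transcription factor, rose from 2.93 CPM in S1 to 1247 ± 994 CPM in C1 (log2 fold change ± SE 8.73 ± 1.04, 7.99 without C1 replicate 2, adjusted p = 4.83e-08). NCED3 rose from 0.342 CPM in S1 to 26.9 ± 11.8 CPM in C1 (6.27 ± 1.01, adjusted p = 6.77e-06), and the mitochondrial alternative oxidase AOX1A (LOC_Os04g51150) from 7.97 CPM in S1 to 319 ± 61.6 CPM in C1 (5.32 ± 0.72, adjusted p = 4.09e-07). The plasma membrane aquaporin PIP2;4 (LOC_Os07g26630) fell from 907 CPM in S1 to 29.4 ± 10.6 CPM in C1 (adjusted p = 2.3e-12). The clock gene PRR95 rose from 7.53 CPM in S1 to 1314 ± 386 CPM in C1 (7.45 ± 0.58, adjusted p = 1.37e-11).

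In the abscisic acid list 10 of 13 tested members rose, 1 fell and 2 did not pass (11 up and 1 down adjusted over the list alone), among them the catabolic hydroxylase ABA8ox1 (LOC_Os02g47470, 4.71 ± 0.73), PP2C50 (2.91 ± 0.41) and PP2C09 (2.75 ± 0.83). Abscisic acid genes had a camera adjusted p of 2.6e-05, and adjusted p = 0.0681 with an estimated correlation. Of the cold regulators, 13 of 20 tested members rose and 7 did not pass (14 up adjusted over the list alone), with NAC6 (LOC_Os01g66120, 7.18 ± 1.01, 6.59 without C1 replicate 2), DREB2B (LOC_Os05g27930, 4.13 ± 0.39), MYBS3 (LOC_Os10g41200, 2.79 ± 0.40), NAC5 (2.68 ± 0.56) and bZIP23 (LOC_Os02g52780, 2.31 ± 0.42). Cold regulators gave a camera adjusted p of 2.92e-07, and adjusted p = 0.0681 with an estimated correlation. In jasmonate synthesis and its JAZ repressors, 10 of 12 tested members rose and 2 did not pass (10 up and 1 down adjusted over the list alone), with JAZ11 (LOC_Os03g08320, 7.82 ± 1.26, 7.05 without C1 replicate 2) and JAZ12 (LOC_Os10g25290, 6.22 ± 0.96). Jasmonate genes reached a camera adjusted p of 1.14e-06, and adjusted p = 0.0757 with an estimated correlation. Of dehydrins and osmoprotection genes, 11 of 17 tested members rose, 1 fell and 5 did not pass (11 up and 1 down adjusted over the list alone). Dehydrin genes had a camera adjusted p of 0.00016, and adjusted p = 0.04 with an estimated correlation. LEA3-1 (LOC_Os05g46480, 4.09 ± 1.22, 4.70 without C1 replicate 3) was one that rose, a call that ended when only C1 and S1 were fitted (4.29). With a class term the log2 fold change was 2.93 for LEA3-1 and 6.59 for NAC6. In defence, 5 of 10 tested members rose and 5 did not pass (5 up adjusted over the list alone), including the salicylate regulator NPR1 (LOC_Os01g09800, 2.67 ± 0.37). Defence genes gave a camera adjusted p of 0.000286, and adjusted p = 0.0757 with an estimated correlation. For the clock, 4 of 9 tested members rose and 5 did not pass (4 up adjusted over the list alone), with PRR1 (3.26 ± 0.30). Clock genes reached a camera adjusted p of 7.4e-05, and adjusted p = 0.0681 with an estimated correlation. Antioxidant enzymes and oxidases rose more often than they fell: 5 of 13 tested members rose, 1 fell and 7 did not pass (5 up and 1 down adjusted over the list alone). Antioxidant genes had a camera adjusted p of 0.0458, and adjusted p = 0.223 with an estimated correlation. Of shoot photosynthesis markers, 5 of 13 tested members rose and 8 did not pass (5 up adjusted over the list alone). Photosynthesis markers gave a camera adjusted p of 0.00749, and adjusted p = 0.0757 with an estimated correlation.

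Aquaporins fell in most cases: 11 of 14 tested members fell and 3 did not pass (11 down adjusted over the list alone). Aquaporins reached a camera adjusted p of 9.71e-07, and adjusted p = 0.0681 with an estimated correlation. The range ran from PIP1;1 (LOC_Os02g44630, -2.30 ± 0.24) over PIP2;3 (LOC_Os04g44060, -2.81 ± 0.27), PIP2;5 (LOC_Os07g26660, -2.87 ± 0.46), PIP2;1 (LOC_Os07g26690, -2.95 ± 0.21), TIP2;1 (LOC_Os02g44080, -3.12 ± 0.54) and NIP2;1 (LOC_Os02g51110, -3.59 ± 0.48) to PIP2;4 (-4.95 ± 0.34). NIP2;1, a silicon channel also called LSI1, stands among the root zone markers too, where 2 of 4 tested members fell and 2 did not pass (2 down adjusted over the list alone). Root zone markers had a camera adjusted p of 0.103. The remaining lists did not pass. Their camera adjusted p-values were 0.0612 for cell division, 0.524 for cytokinin, 0.297 for ethylene synthesis, 0.524 for fermentation, 0.484 for gibberellin, 0.484 for heat shock, 0.551 for secondary wall, 0.88 for nutrient uptake and 0.524 for sugar use. Single members still moved: the replication factor PCNA (LOC_Os02g56130, -2.71 ± 0.38) and the cytokinin response regulators RR4 (LOC_Os01g72330, -2.23 ± 0.31) and RR2 (LOC_Os02g35180, -1.93 ± 0.28) fell. The cytokinin-activating LOG (LOC_Os01g40630, 4.43 ± 0.59), the ethylene synthesis gene ACS2 (LOC_Os04g48850, 3.16 ± 0.66), the phosphate signalling gene SPX1 (LOC_Os06g40120, 2.85 ± 0.42) and the sucrose transporter SUT1 (LOC_Os03g07480, 2.97 ± 0.63) rose. The potassium channel AKT1 (LOC_Os01g45990, -2.76 ± 0.53) fell. Adjusted p of the genes named was at most 0.00703.

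The test called 12165 loci, 4982 up and 7183 down (41.0% up). With DESeq2's size factors 5881 rose and 5780 fell (50.4% up), and DESeq2 gave 51.7% up. The median log2 fold change of all loci was -0.18 with TMM and 0.01 with DESeq2's factors for C1. It was -0.19 and 0 for C-R1, and 0.02 and 0.13 for C-L1. S1 was of the low class, in which 11718 loci changed (1 against 1). Fitting only C1 and S1 gave 2558. Against the 7 untreated libraries the fold change in C1 moved by over 1.5 times for 13 of these genes. On the log2 scale it moved to 5.96 for WRKY71, 5.47 for NAC6, 3.99 for AOX1A, 3.84 for JAZ11 and 3.71 for JAZ12. Further log2 values were 3.68 for LOG, 2.59 for LEA3-1, 2.44 for ACS2, 1.58 for PP2C09 and 1.56 for bZIP23. Negative ones were -1.78 for PCNA, -2.09 for AKT1 and -2.24 for TIP2;1.

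Cold on the roots alone (C-R1, n = 3) raised 11 of 13 tested abscisic acid, 10 of 12 jasmonate and 11 of 17 dehydrin genes against the single S1 library, and 9 of 14 aquaporins and 6 of 7 cell division genes were lower than in C1. Of these only the dehydrin list passed with an estimated correlation (adjusted p = 0.0216, others 0.0986 to 0.682). The vacuolar aquaporin TIP1;1 fell from 2197 CPM in S1 to 51.1 ± 9.50 CPM in C-R1 (log2 fold change ± SE -5.42 ± 0.48, adjusted p = 2.1e-10), and in the direct comparison it was lower than in C1 (-1.66 ± 0.37, adjusted p = 0.00109). CASP1 (LOC_Os04g58760), a protein of the Casparian strip, fell from 139 CPM in S1 to 2.56 ± 0.417 CPM in C-R1 (adjusted p = 6.36e-10) and was -3.32 ± 0.45 relative to C1. NCED3 (6.31 ± 1.02) and AOX1A (5.47 ± 0.72) rose, and neither differed from C1 by the test (0.04 ± 0.45 and 0.15 ± 0.36, adjusted p = 0.967 and 0.798). The NCED3 difference was -0.10 without C1 replicate 1, -0.09 without C1 replicate 3 and -0.15 without C-R1 replicate 1, and that of AOX1A -0.09 without C-R1 replicate 1.

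Against S1, among aquaporins 13 of 14 tested members fell and 1 did not pass (13 down adjusted over the list alone), with TIP2;1 (-4.46 ± 0.54), PIP2;3 (-4.36 ± 0.27), PIP1;2 (-4.21 ± 0.45) and PIP2;1 (-3.94 ± 0.21). Aquaporins gave a camera adjusted p of 8.66e-09, and adjusted p = 0.0519 with an estimated correlation. Relative to C1, 1 of 14 tested members rose, 9 fell and 4 did not pass (1 up and 10 down adjusted over the list alone), among them TIP2;2 (-1.82 ± 0.38), PIP2;3 (-1.55 ± 0.21) and PIP1;1 (-0.94 ± 0.19). Aquaporins reached a camera adjusted p of 0.00526, and adjusted p = 0.682 with an estimated correlation. Of the cell division genes, 7 of 7 tested members fell (7 down adjusted over the list alone) against S1, with CYCB2;1 (LOC_Os04g47580, -2.91 ± 0.33), CYCB1;1 (LOC_Os01g59120, -2.39 ± 0.49), CDKB2;1 (LOC_Os08g40170, -2.21 ± 0.38) and PCNA (-3.36 ± 0.38). Cell division genes had a camera adjusted p of 0.000443, and adjusted p = 0.246 with an estimated correlation. Relative to C1, 6 of 7 tested members fell and 1 did not pass (7 down adjusted over the list alone), including CYCB1;1 (-1.94 ± 0.40) and CDKB2;1 (-1.49 ± 0.30). Cell division genes gave a camera adjusted p of 0.00372, and adjusted p = 0.682 with an estimated correlation.

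Of the abscisic acid list, 11 of 13 tested members rose, 1 fell and 1 did not pass (11 up and 1 down adjusted over the list alone), with PP2C49 (LOC_Os05g38290, 4.89 ± 1.29) and PP2C09 (3.54 ± 0.87). Abscisic acid genes reached a camera adjusted p of 2.85e-05, and adjusted p = 0.0986 with an estimated correlation. ABA8ox1 was lower than in C1 (-2.40 ± 0.40, adjusted p = 3.94e-05). For cold regulators, 14 of 20 tested members rose and 6 did not pass (14 up adjusted over the list alone), with NAC6 (5.55 ± 0.93), DREB2B (3.46 ± 0.38) and DREB2A (LOC_Os01g07120, 1.71 ± 0.29). Cold regulators had a camera adjusted p of 3.04e-06, and adjusted p = 0.103 with an estimated correlation. Relative to C1 DREB2A was higher (1.31 ± 0.19) and MYBS3 lower (-1.29 ± 0.24). In the jasmonate list 10 of 12 tested members rose and 2 did not pass (10 up adjusted over the list alone), with JAZ11 (7.26 ± 1.23) and JAZ12 (5.84 ± 0.94). Jasmonate genes gave a camera adjusted p of 2.79e-06, and adjusted p = 0.108 with an estimated correlation. For dehydrins, 11 of 17 tested members rose, 1 fell and 5 did not pass (11 up and 1 down adjusted over the list alone), including LIP9 (LOC_Os02g44870, 3.90 ± 0.78). Dehydrin genes reached a camera adjusted p of 5.56e-05, and adjusted p = 0.0216 with an estimated correlation. In defence 7 of 10 tested members rose, 1 fell and 2 did not pass (7 up and 1 down adjusted over the list alone), and the list did not pass with the 7 untreated libraries as the control. Defence genes had a camera adjusted p of 0.00231, and adjusted p = 0.176 with an estimated correlation. WRKY71 rose (6.49 ± 0.94) and was below C1 (-2.24 ± 0.45, -1.34 without C1 replicate 2, adjusted p = 0.000376). For the clock, 6 of 9 tested members rose and 3 did not pass (6 up adjusted over the list alone), among them PRR95 (6.97 ± 0.56) and GI (LOC_Os01g08700, 1.21 ± 0.41). Clock genes gave a camera adjusted p of 0.000217, and adjusted p = 0.0986 with an estimated correlation. The sucrose exporter SWEET14 (LOC_Os11g31190, 2.55 ± 0.56) and AMT1;1 (1.90 ± 0.57) rose and exceeded C1 (2.38 ± 0.36 and 1.67 ± 0.37, 2.35 without C1 replicate 3). Shoot photosynthesis markers did not pass against S1 (camera adjusted p = 0.432), and relative to C1 7 of 13 tested members fell and 6 did not pass (8 down adjusted over the list alone). Photosynthesis markers reached a camera adjusted p of 0.00579, and adjusted p = 0.322 with an estimated correlation. Adjusted p of the examples was at most 0.0149 against S1.

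Against S1 12855 loci changed (5112 up, 7743 down, 39.8% up, and 48.2% with DESeq2's factors and 49.8% in DESeq2), 13799 within the low class (2 against 1). Relative to C1, 7435 loci differed, 3382 higher and 4053 lower in C-R1, 3229 within the low class (2 against 1) and 9773 within the high class (1 against 2). A fit of C-R1 and C1 alone called 1881. C-R1 plants also differed from C1 in vessel, medium and air temperature. Against the 7 untreated libraries the fold change in C-R1 moved by over 1.5 times for 15 of these genes. On the log2 scale it moved to 4.27 for PP2C49, 4.15 for AOX1A, 3.83 for NAC6, 3.72 for WRKY71 and 3.33 for JAZ12. Further log2 values were 3.28 for SWEET14, 3.27 for JAZ11, 3.16 for LIP9 and 2.37 for PP2C09. Negative ones were -1.48 for CDKB2;1, -1.55 for CYCB1;1, -2.10 for CYCB2;1, -2.43 for PCNA, -3.57 for TIP2;1 and -4.73 for CASP1.

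Roots of plants whose leaves alone were cold (C-L1, n = 3) kept a medium of 20 °C and differed from the single S1 library in falls of 7 of 7 tested cell division, 3 of 3 secondary wall and 4 of 5 fermentation genes. These lists did not pass with an estimated correlation (adjusted p = 0.204, 0.18 and 0.18). The cellulose synthase CESA4 (LOC_Os01g54620) fell from 194 CPM in S1 to 10.6 ± 5.14 CPM in C-L1 (log2 fold change ± SE -4.20 ± 0.47, adjusted p = 1.43e-08) and the mitotic cyclin CYCB2;2 (LOC_Os06g51110) from 50.9 CPM in S1 to 5.19 ± 3.68 CPM in C-L1 (-3.30 ± 0.47, -4.03 without C-L1 replicate 3, adjusted p = 1.04e-06). NCED3 rose from 0.342 CPM in S1 to 6.24 ± 4.16 CPM in C-L1 (4.16 ± 0.94, 3.46 without C-L1 replicate 3, adjusted p = 0.000745), less than in C1 (difference -2.11 ± 0.48, -2.80 without C-L1 replicate 3, adjusted p = 0.000299). HB1 fell from 167 CPM in S1 to 2.97 ± 2.44 CPM in C-L1 (-5.83 ± 0.66, -6.74 without C-L1 replicate 3, adjusted p = 1.79e-08).

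In the cell division list 7 of 7 tested members fell (7 down adjusted over the list alone), with PCNA (-3.08 ± 0.38), CYCB2;1 (-2.14 ± 0.33) and CDKB1;1 (LOC_Os01g67160, -1.97 ± 0.28). Cell division genes had a camera adjusted p of 3.94e-05, and adjusted p = 0.204 with an estimated correlation. For secondary wall, 3 of 3 tested members fell (3 down adjusted over the list alone), the others being CESA7 (LOC_Os10g32980, -4.04 ± 0.65, -4.70 without C-L1 replicate 3) and CESA9 (LOC_Os09g25490, -3.97 ± 0.51). Secondary wall genes gave a camera adjusted p of 0.00278, and adjusted p = 0.18 with an estimated correlation. Of the fermentation list, 4 of 5 tested members fell and 1 did not pass (4 down adjusted over the list alone), with PDC2 (-1.86 ± 0.31) and ADH1 (LOC_Os11g10480, -1.64 ± 0.45). Fermentation genes reached a camera adjusted p of 0.00628, and adjusted p = 0.18 with an estimated correlation. Shoot photosynthesis markers went up: 8 of 13 tested members rose and 5 did not pass (9 up adjusted over the list alone), among them the rubisco activase RCA (LOC_Os11g47970, 3.93 ± 1.40) at 3.08 ± 0.944 CPM. Photosynthesis markers had a camera adjusted p of 5.59e-05, and adjusted p = 0.0316 with an estimated correlation. For nutrient uptake, 6 of 18 tested members fell and 12 did not pass (7 down adjusted over the list alone), with the ammonium transporters AMT1;3 (LOC_Os02g40730, -4.89 ± 0.64, -5.69 without C-L1 replicate 3) and AMT1;1 (-2.27 ± 0.46), the phosphate transporter PT2 (LOC_Os03g05640, -2.37 ± 0.72) and the nitrate transport partner NAR2.1 (LOC_Os02g38230, -2.98 ± 0.58). Nutrient uptake genes gave a camera adjusted p of 0.0359, and adjusted p = 0.439 with an estimated correlation. Among aquaporins 7 of 14 tested members fell and 7 did not pass (8 down adjusted over the list alone), with TIP2;1 (-4.05 ± 0.54, -4.68 without C-L1 replicate 3), PIP1;2 (-1.79 ± 0.46) and PIP2;1 (-1.61 ± 0.22). Aquaporins reached a camera adjusted p of 0.00628, and adjusted p = 0.417 with an estimated correlation. In the cold regulator list 7 of 20 tested members rose and 13 did not pass (10 up adjusted over the list alone), with NAC6 (3.65 ± 0.83) and MYBS3 (2.18 ± 0.39). Cold regulators had a camera adjusted p of 0.0051, and adjusted p = 0.417 with an estimated correlation. For defence, 6 of 10 tested members rose and 4 did not pass (6 up adjusted over the list alone), and the list did not pass with the 7 untreated libraries as the control. Defence genes gave a camera adjusted p of 0.0051, and adjusted p = 0.266 with an estimated correlation. Examples were WRKY71 (4.39 ± 0.84), WRKY62 (LOC_Os09g25070, 3.35 ± 0.85) and NPR1 (2.80 ± 0.37). SUT1 (3.23 ± 0.64) and SWEET14 (2.55 ± 0.56) rose, and the sucrose synthase SUS1 (LOC_Os03g28330, -3.08 ± 0.35) fell. Adjusted p of these genes was at most 0.0275.

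Directly compared, C-L1 was higher than C-R1 in 12 of 14 tested aquaporins and lower in 10 of 13 abscisic acid, 11 of 12 jasmonate and 13 of 17 dehydrin genes and in AOX1A. Of these only the dehydrin list passed with an estimated correlation (adjusted p = 0.0395, others 0.155 to 0.201). PIP2;3 was 3.18 ± 0.23 (log2 ± SE) relative to C1 and 4.73 ± 0.24 relative to C-R1, and AOX1A -5.59 ± 0.44 and -5.74 ± 0.44. LIP9 was -3.30 ± 0.47 relative to C1 and -3.42 ± 0.47 relative to C-R1, and the clock gene PRR95 -5.28 ± 0.31 and -4.80 ± 0.30 (adjusted p of the 4 genes at most 3.05e-07). Relative to C-R1, among aquaporins 12 of 14 tested members rose and 2 did not pass (12 up adjusted over the list alone). Aquaporins reached a camera adjusted p of 5.93e-05, and adjusted p = 0.155 with an estimated correlation. In the abscisic acid list 1 of 13 tested members rose, 10 fell and 2 did not pass (1 up and 11 down adjusted over the list alone), and in the jasmonate list 11 of 12 tested members fell and 1 did not pass (11 down adjusted over the list alone). Abscisic acid genes had a camera adjusted p of 0.00334, and adjusted p = 0.195 with an estimated correlation. Jasmonate genes gave a camera adjusted p of 0.000312, and adjusted p = 0.201 with an estimated correlation. For dehydrins 2 of 17 tested members rose, 13 fell and 2 did not pass (2 up and 13 down adjusted over the list alone). Dehydrin genes reached a camera adjusted p of 0.000312, and adjusted p = 0.0395 with an estimated correlation. For fermentation 5 of 5 tested members fell (5 down adjusted over the list alone), and for the clock 2 of 9 tested members rose, 6 fell and 1 did not pass (2 up and 6 down adjusted over the list alone). Fermentation genes had a camera adjusted p of 0.00572, and adjusted p = 0.155 with an estimated correlation. Clock genes gave a camera adjusted p of 0.00621, and adjusted p = 0.195 with an estimated correlation. Examples were TIP1;1 (3.77 ± 0.40), PIP2;4 (3.87 ± 0.29), ABA8ox1 (-2.41 ± 0.40, -3.12 without C-L1 replicate 3), JAZ12 (-2.84 ± 0.48), OPR7 (LOC_Os08g35740, -1.69 ± 0.10), ADH1 (-4.42 ± 0.38) and GI (-3.50 ± 0.30), while the morning gene LHY (LOC_Os08g06110, 1.49 ± 0.22) and ELF3 (LOC_Os06g05060, 1.29 ± 0.19) were higher in C-L1. Relative to C1, cell division genes were lower, as 6 of 7 tested members fell and 1 did not pass (6 down adjusted over the list alone), whereas relative to C-R1 they did not pass (camera adjusted p = 0.816). Cell division genes reached a camera adjusted p of 0.015, and adjusted p = 0.396 with an estimated correlation. In the shoot photosynthesis list 9 of 13 tested members rose and 4 did not pass (9 up adjusted over the list alone) relative to C-R1. Photosynthesis markers had a camera adjusted p of 0.00572, and adjusted p = 0.155 with an estimated correlation. Further lists past the camera test relative to C-R1 were antioxidant (6 down of 13, adjusted p = 0.012), cold regulator (1 up and 7 down of 20, 0.0165), secondary wall (3 down of 3, 0.0191) and nutrient uptake (2 up and 11 down of 18, 0.0107). Adjusted over the list alone the counts were 6 down (antioxidant), 1 up and 7 down (cold regulator), 3 down (secondary wall), 2 up and 11 down (nutrient uptake). With an estimated correlation these had adjusted p = 0.195, 0.407, 0.222 and 0.375. Relative to C1 aquaporins were higher, and stress lists lower, by the camera test: aquaporin (10 up of 14, adjusted p = 0.00197), abscisic acid (1 up and 10 down of 13, 0.00225), jasmonate (10 down of 12, 0.000405), dehydrin (2 up and 13 down of 17, 0.000907) and antioxidant (12 down of 13, 0.000709). Adjusted over the list alone the counts were 11 up and 2 down (aquaporin), 1 up and 11 down (abscisic acid), 10 down (jasmonate), 2 up and 14 down (dehydrin), 12 down (antioxidant). In the same order they had adjusted p = 0.257, 0.205, 0.205, 0.0687 and 0.0882 with an estimated correlation. Other lists lower relative to C1 were cold regulator (1 up and 10 down of 20, adjusted p = 0.00197), fermentation (5 down of 5, 0.00197), clock (2 up and 7 down of 9, 0.00295), secondary wall (3 down of 3, 0.0103) and nutrient uptake (2 up and 11 down of 18, 0.0368). Adjusted over the list alone the counts were 1 up and 10 down (cold regulator), 5 down (fermentation), 2 up and 7 down (clock), 3 down (secondary wall), 2 up and 11 down (nutrient uptake). With an estimated correlation these had adjusted p = 0.257, 0.0936, 0.205, 0.205 and 0.44.

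Against S1 9228 loci changed (3859 up, 5369 down, 41.8% up, and 47.5% with DESeq2's factors and 51.2% in DESeq2), 11619 within the low class (2 against 1) and 5348 when C-L1 and S1 alone were fitted. C-L1 differed from C1 at 15113 loci (12155 within the low and 14171 within the high class) and from C-R1 at 15117 (15273 and 12198). Of the loci changed by acclimation alone, 1851 were also called in C1 and S1 (1424 expected of independent lists), 86.1% of them in the same direction. The shares were 93.9% of 2007 for C-R1 and 59.9% of 1393 for C-L1. Against the 7 untreated libraries the fold change in C-L1 moved by over 1.5 times for 14 of these genes. On the log2 scale it moved to 5.92 for RCA, 3.18 for SWEET14, 1.81 for NAC6, 1.64 for WRKY62 and 1.495 for WRKY71. Negative log2 values were -1.35 for CDKB1;1, -1.46 for CYCB2;1, -1.502 for PT2, -2.27 for PCNA and -2.47 for CYCB2;2. The lowest were -3.30 for TIP2;1, -3.60 for CESA4, -3.64 for NAR2.1 and -5.61 for AMT1;3.

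Acclimation before cold on the whole plant (AC1 against C1, n = 3 each) was followed by lower transcripts of HSFA2A, APX2 and HB1 in the cold roots. HSFA2A was lower, from 8.46 ± 7.83 CPM in C1 to 0.240 ± 0.0864 CPM in AC1 (log2 fold change ± SE -5.07 ± 0.77, -4.20 without C1 replicate 2, adjusted p = 0.000198). APX2 was 392 ± 234 CPM in C1 and 135 ± 4.0 CPM in AC1 (-1.53 ± 0.23, adjusted p = 0.000173), and HB1 71.0 ± 15.1 CPM in C1 and 15.5 ± 4.17 CPM in AC1 (-2.19 ± 0.50, adjusted p = 0.00767). The phosphate transporter PT6 (LOC_Os08g45000) was higher, from 0.689 ± 0.230 CPM in C1 to 18.5 ± 15.2 CPM in AC1 (4.73 ± 0.80, adjusted p = 0.000596), as was SWEET14 at 1.66 ± 0.35, not passing without C1 replicate 2 (1.42).

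Of the cold regulators, 5 of 20 tested members fell and 15 did not pass (6 down adjusted over the list alone) relative to C1. Cold regulators gave a camera adjusted p of 0.00102, and adjusted p = 0.349 with an estimated correlation. In the jasmonate list 5 of 12 tested members fell and 7 did not pass (9 down adjusted over the list alone), among them JAZ9 (LOC_Os03g08310) at -3.89 ± 0.72, not passing without C1 replicate 2 (-1.21), which ranged widely in C1 (101 ± 148 CPM) against 6.82 ± 1.65 in AC1. Jasmonate genes reached a camera adjusted p of 0.000249, and adjusted p = 0.349 with an estimated correlation. Of dehydrins 4 of 17 tested members fell and 13 did not pass (10 down adjusted over the list alone). Dehydrin genes had a camera adjusted p of 0.000249, and adjusted p = 0.0271 with an estimated correlation. Of cell division genes 1 of 7 tested members fell and 6 did not pass (4 down adjusted over the list alone), and of shoot photosynthesis markers 1 of 13 tested members fell and 12 did not pass (1 down adjusted over the list alone). Cell division genes gave a camera adjusted p of 0.00817, and adjusted p = 0.47 with an estimated correlation. Photosynthesis markers reached a camera adjusted p of 0.0307, and adjusted p = 0.349 with an estimated correlation. In nutrient uptake 3 of 18 tested members rose and 15 did not pass (3 up adjusted over the list alone). Nutrient uptake genes had a camera adjusted p of 0.0271, and adjusted p = 0.498 with an estimated correlation. The test called 1520 loci, 549 higher and 971 lower in AC1, and 1709 within the low class (1 against 1) and 8522 within the high class (2 against 2). Of 774 loci called in both, 24.5% went in the same direction. The low-class side sets a single library against another, with the spread taken from other groups, so it does not describe a class. The count was 722 without AC1 replicate 2, 414 without AC1 replicate 3, 331 without C1 replicate 2 and 3980 without C1 replicate 3. With only AC1 and C1 in the fit 0 loci passed, which ended the calls named (HSFA2A did not enter that fit), against DESeq2's 2202 and 5504 at an unadjusted p under 0.05 with all groups fitted.

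Acclimation before cold on the roots (AC-R1 against C-R1, n = 3 each) was followed by higher transcripts of CASP1, the aquaporin PIP2;1 and the sucrose synthase SUS1. CASP1 rose from 2.56 ± 0.417 CPM in C-R1 to 14.2 ± 3.53 CPM in AC-R1 (log2 fold change ± SE 2.45 ± 0.44, adjusted p = 0.00163) and PIP2;1 from 92.5 ± 9.54 CPM in C-R1 to 169.9 ± 21.3 CPM in AC-R1 (0.88 ± 0.17, adjusted p = 0.00257). SUS1 was higher by 1.27 ± 0.28, not passing without C-R1 replicate 1 (1.22). Their lists did not pass: of aquaporins 2 of 14 tested members rose and 12 did not pass (2 up adjusted over the list alone), in sugar use 1 of 6 tested members rose and 5 did not pass (1 up adjusted over the list alone) and of root zone markers 1 of 4 tested members rose and 3 did not pass (1 up adjusted over the list alone). Aquaporins gave a camera adjusted p of 0.103. Sugar use genes reached a camera adjusted p of 0.443. Root zone markers had a camera adjusted p of 0.121. In the jasmonate list 1 of 12 tested members fell and 11 did not pass (1 down adjusted over the list alone), the one that fell being JAR1 (LOC_Os05g50890), which conjugates jasmonate to isoleucine, at -0.85 ± 0.19, not passing without AC-R1 replicate 1 (-0.67) or C-R1 replicate 1 (-0.79). Jasmonate genes gave a camera adjusted p of 0.0243, and adjusted p = 0.658 with an estimated correlation. In the fermentation list 0 of 5 tested members passed (2 down adjusted over the list alone). Fermentation genes reached a camera adjusted p of 0.0363 (downward), and adjusted p = 0.395 with an estimated correlation. Between AC-R1 and C-R1 1130 loci changed, 566 up and 564 down, with 716 within the low class (2 against 2) and 6185 within the high class (1 against 1). AC-R1 replicate 1, the high-class library, lay apart from its group on the first component. Without it 311 loci passed, without C-R1 replicate 1 176 and without C-R1 replicate 3 578. A fit of only these groups gave 0 (DESeq2 1872 and 5184 at an unadjusted p under 0.05, all groups fitted), ending the calls named.

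Acclimation before cold on the leaves (AC-L1 against C-L1, n = 3 each) was followed by higher transcripts of 4 of 7 tested cell division genes in the roots, a list that did not pass with an estimated correlation (adjusted p = 0.507). Of the cell division list, 4 of 7 tested members rose and 3 did not pass (7 up adjusted over the list alone), among them CDKB2;1, which rose from 11.2 ± 7.59 CPM in C-L1 to 26.6 ± 3.51 CPM in AC-L1 (log2 fold change ± SE 1.26 ± 0.30, adjusted p = 0.0167), not passing without AC-L1 replicate 2 (1.15), C-L1 replicate 1 (0.97) or C-L1 replicate 2 (1.03), 1.97 without C-L1 replicate 3. Cell division genes had a camera adjusted p of 3.15e-06, and adjusted p = 0.507 with an estimated correlation. Of aquaporins 1 of 14 tested members rose and 13 did not pass (1 up adjusted over the list alone), of nutrient uptake genes 1 of 18 tested members rose and 17 did not pass (1 up adjusted over the list alone) and of secondary wall genes 0 of 3 tested members passed (3 up adjusted over the list alone). Aquaporins gave a camera adjusted p of 0.00217, and adjusted p = 0.55 with an estimated correlation. Nutrient uptake genes reached a camera adjusted p of 0.0193, and adjusted p = 0.559 with an estimated correlation. Secondary wall genes had a camera adjusted p of 0.0193 (upward), and adjusted p = 0.55 with an estimated correlation. Between AC-L1 and C-L1 1003 loci changed, 660 up and 343 down (65.8% up, 59.1% with DESeq2's factors and 51.5% in DESeq2). The AC-L1 libraries were all of the high class and 2 of the C-L1 libraries of the low class. Within the high class (3 against 1) 45 loci changed, the low class holding no AC-L1 library, and 637 were called with a class term, 559 of them among the 1003. The count was 279, 129 and 659 without AC-L1 replicates 1, 2 and 3, and 0, 28 and 3305 without C-L1 replicates 1, 2 and 3. A fit of only these groups gave 0, ending the calls named (DESeq2 2236 and 5578 at an unadjusted p under 0.05, all groups fitted).

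The acclimation differences of whole-plant and root cold overlapped: 253 loci were called in both, 65.8 being the number for independent lists, and 98.8% of them had the same direction. Whole-plant and leaf cold shared 82 (58.4 for independent lists, 57.3% in the same direction), and root and leaf cold 73 (43.4 and 74.0%). AC1 and C1 held the same class numbers, as did AC-R1 and C-R1, but AC-L1 and C-L1 did not. Class may therefore enter a test across the cold targets. An interaction test over the 18 libraries of these groups found 962 of 26120 loci at which the acclimation difference varied with the cold target. With a class term it found 1239, and DESeq2 2385. At an unadjusted p under 0.05 it found 5708, where evenly spread p-values would give 1306. The main count of 962 depended on single libraries. Leaving out 1 library moved that count by more than 1.5 times for 10 libraries: 1552 without AC1 replicate 1, 540 without AC1 replicate 3, 381 without AC-L1 replicate 1, 368 without AC-L1 replicate 2, 5.2e+02 without C1 replicate 2, 3716 without C1 replicate 3, 235 without C-L1 replicate 1, 382 without C-L1 replicate 2, 2362 without C-L1 replicate 3 and 598 without C-R1 replicate 1.

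**Figure D2:**
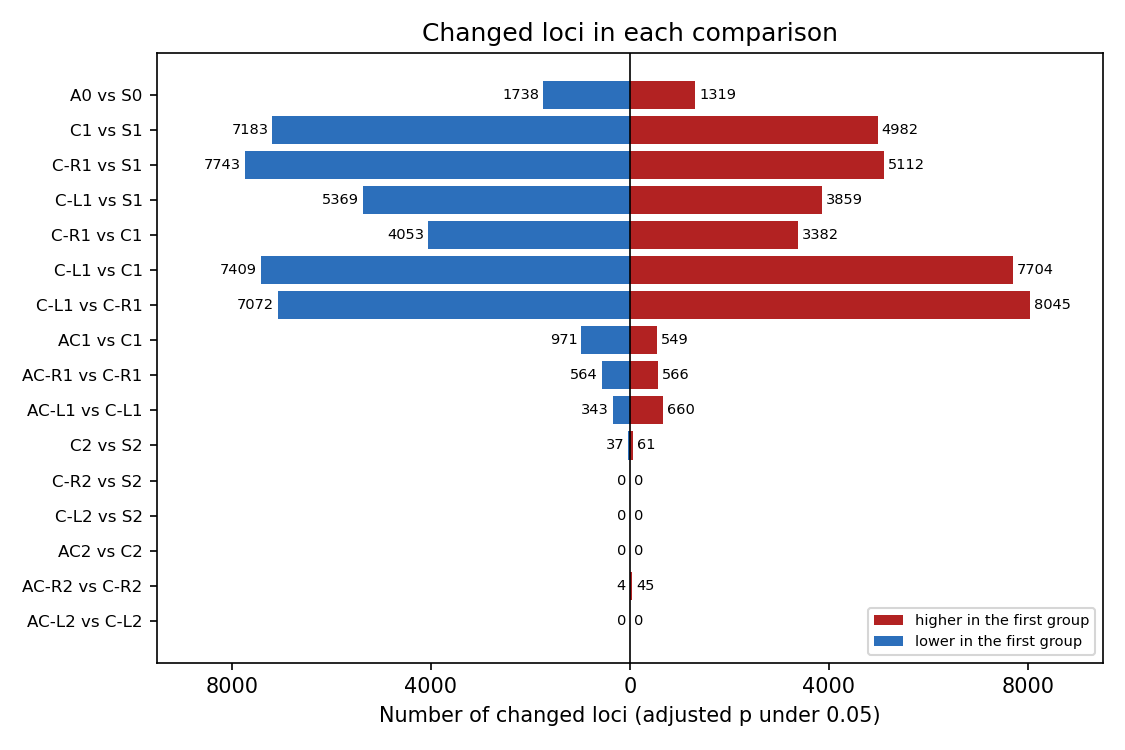
Bars give the number of loci with an adjusted p under 0.05 in each of the 16 comparisons, higher (right) or lower (left) in the group named first. C-L1 against C-R1 has 8045 and 7072, AC1 against C1 549 and 971, and C-R2, C-L2, AC2 and AC-L2 against their reference groups 0.

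After 3 days of recovery, NCED3, PIP2;1 and CESA4 did not pass the test between roots after cold and untreated roots at 17 days, while some gene lists passed the camera test, but none with an estimated correlation (lowest adjusted p = 0.103 for C2, 0.128 for C-R2 and 0.436 for C-L2). NCED3, 26.9 ± 11.8 CPM in C1, was at 0.385 ± 0.371 CPM in C2 and 0.253 ± 0.0738 in S2, a log2 difference of 0.65 ± 0.73 (adjusted p = 0.847), which was -0.52 without C2 replicate 1. PIP2;1 stood at 1407 ± 71.3 CPM in C2 and 1099.7 ± 119 in S2 (0.36 ± 0.17, adjusted p = 0.402), and CESA4, lowered in C-L1, differed by -0.19 ± 0.36 (adjusted p = 1) between C-L2 and S2, and by 0.02 without C-L2 replicate 1 and 0.18 without S2 replicate 2. CASP1 was higher in C2 than in S2, from 55.6 ± 15.3 CPM in S2 to 183 ± 19.3 CPM in C2 (1.72 ± 0.40, adjusted p = 0.0428). That call ended with DESeq2's size factors, and without C2 replicate 1 (1.70), C2 replicate 2 (1.65), C2 replicate 3 (1.80), S2 replicate 1 (1.61) or S2 replicate 3 (1.60).

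For whole-plant cold, 98 loci differed between C2 and S2 (61 up, 37 down, 62.2% up, 50.8% with DESeq2's factors), 311 up and 213 down in DESeq2 and 2678 within the high class (2 against 2), 1 within the low class (1 against 1). Of these 98, 69 had also been called in C1 and S1 (45.6 for independent lists), 92.8% of them in the opposite direction. The count was 4, 0 and 0 without C2 replicates 1, 2 and 3, and 14, 170 and 0 without S2 replicates 1, 2 and 3. In the fermentation list 0 of 5 tested members passed (4 down adjusted over the list alone), HB1 being at 101 ± 21.5 CPM in C2 and 347 ± 169 in S2 (-1.78 ± 0.49, adjusted p = 0.0798). Fermentation genes gave a camera adjusted p of 0.00141 (downward), and adjusted p = 0.103 with an estimated correlation. HB1 passed in DESeq2 (-1.82, adjusted p = 0.0175), with a class term (-1.78, adjusted p = 0.0439) and when only C2 and S2 were fitted (-1.81, adjusted p = 0.0467). Also past the camera test were jasmonate (down, adjusted p = 0.00505), cell division (up, 0.0101) and antioxidant (down, 0.0191). There 0 of 12, 7 and 13 members passed, and 2 down (jasmonate) and 2 down (antioxidant) did adjusted over the list alone. In the same order they had adjusted p = 0.646, 0.646 and 0.474 with an estimated correlation. Between C-R2 and S2 edgeR called 0 loci (2817 at an unadjusted p under 0.05 and 67 in DESeq2, 11 without S2 replicate 2 and 1 without S2 replicate 3). Within the low class (3 against 1) 1 passed, and the high class held no C-R2 library. Between C-L2 and S2 edgeR called 0 (1181 at an unadjusted p under 0.05 and 22 in DESeq2, 7 without S2 replicate 2), and 3 within the low class (1 against 1) and 646 within the high class (2 against 2). Past the camera test between C-R2 and S2 were fermentation (down, adjusted p = 0.00223), cold regulator (down, 0.00557), cytokinin (down, 0.00972), abscisic acid (down, 0.0147) and heat shock (down, 0.0312). There 0 of 5, 20, 16, 13 and 4 members passed, and 3 down (fermentation) and 1 down (heat shock) did adjusted over the list alone. With an estimated correlation these had adjusted p = 0.128, 0.467, 0.411, 0.467 and 0.467. Between C-L2 and S2 they were jasmonate (down, adjusted p = 0.00519) and cell division (up, 0.00641). There 0 of 12 and 7 members passed, and none adjusted over the list alone. In the same order they had adjusted p = 0.534 and 0.534 with an estimated correlation.

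Roots of plants acclimated before root cold held more transcripts of a nitrate and an iron transporter after recovery (AC-R2 against C-R2, n = 3 each), in 2 of 3 libraries. AC-R2 replicates 2 and 3 were of the high class, and AC-R2 replicate 1 and all C-R2 libraries of the low class. Class and acclimation therefore cannot be told apart for this difference. The nitrate transporter NRT2.1 (LOC_Os02g02170) was at 0.488, 68.8 and 122 CPM in AC-R2 replicates 1, 2 and 3 and at most 0.373 CPM in C-R2 (9.05 ± 1.57, adjusted p = 0.0112), not passing without AC-R2 replicate 3 (8.16), C-R2 replicate 1 (8.45), C-R2 replicate 2 (8.46) or C-R2 replicate 3 (13.20). The iron transporter IRT1 (LOC_Os03g46470) was at 7.69 ± 6.78 CPM against 0.307 ± 0.143 (4.60 ± 0.84), not passing without AC-R2 replicate 3 (3.96), C-R2 replicate 1 (4.96), C-R2 replicate 2 (4.61) or C-R2 replicate 3 (4.31). In the nutrient uptake list 4 of 18 tested members rose and 14 did not pass (7 up and 1 down adjusted over the list alone). Nutrient uptake genes reached a camera adjusted p of 0.000796, and adjusted p = 0.405 with an estimated correlation. Other lists past the camera test were cytokinin (up, adjusted p = 0.00318), abscisic acid (up, 0.0167), cold regulator (up, 0.0207), heat shock (up, 0.034), clock (down, 0.0207) and defence (down, 0.034). There 0 of 16, 13, 20, 4, 9 and 10 members passed, and 4 up (cytokinin), 1 up (heat shock) and 1 down (clock) did adjusted over the list alone. With an estimated correlation these had adjusted p = 0.405, 0.405, 0.442, 0.405, 0.405 and 0.405. In all 49 loci differed (45 up, 4 down, 470 in DESeq2), 1 within the low class (1 against 3), where the high class held no C-R2 library, and 1 with a class term. The count was 1983 without AC-R2 replicate 1, 1 without AC-R2 replicate 3 and 0 without C-R2 replicate 1, 2 or 3. The calls of NRT2.1 and IRT1 ended with the class term (8.43 and 3.83). A fit of only AC-R2 and C-R2 gave 0 loci and ended the call of NRT2.1 (9.11), and IRT1 did not enter it.

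Between AC2 and C2 edgeR called 0 loci (2107 at an unadjusted p under 0.05 and 25 in DESeq2, 1 without AC2 replicate 3), with 4 within the low class (1 against 1) and 2858 within the high class (2 against 2), and between AC-L2 and C-L2 0 (1250 at an unadjusted p under 0.05 and 3 in DESeq2), with 80 and 269. As lists, shoot photosynthesis markers were higher in AC-L2 than in C-L2, where 0 of 13 tested members passed (none adjusted over the list alone). Photosynthesis markers had a camera adjusted p of 6.3e-07 (upward), and adjusted p = 0.00522 with an estimated correlation. Nutrient uptake genes were lower, where 0 of 18 tested members passed (5 down adjusted over the list alone). Nutrient uptake genes gave a camera adjusted p of 4.57e-07 (downward), and adjusted p = 0.122 with an estimated correlation. The other lists past the camera test between AC-L2 and C-L2 were jasmonate (down, adjusted p = 0.000246), defence (down, 0.000451), fermentation (down, 0.00408) and dehydrin (up, 0.0485). There 0 of 12, 10, 5 and 17 members passed, and none adjusted over the list alone. In the same order they had adjusted p = 0.268, 0.146, 0.122 and 0.202 with an estimated correlation. Between AC2 and C2 they were shoot photosynthesis (up, adjusted p = 0.00307), cell division (down, 0.00307), jasmonate (up, 0.00531), secondary wall (down, 0.00554), fermentation (up, 0.00559), aquaporin (down, 0.00726), defence (up, 0.00948) and nutrient uptake (up, 0.0322). There 0 of 13, 7, 12, 3, 5, 14, 10 and 18 members passed, and 1 up (shoot photosynthesis), 2 down (secondary wall), 1 up (fermentation) and 3 down (aquaporin) did adjusted over the list alone. With an estimated correlation these had adjusted p = 0.141, 0.412, 0.412, 0.261, 0.214, 0.412, 0.412 and 0.451. The interaction over the recovered groups called 0 of 26120 loci in edgeR, 3183 at an unadjusted p under 0.05 and 147 in DESeq2. It called 733 without AC-R2 replicate 1, 1 without AC-R2 replicate 2 and 1 without AC2 replicate 3.

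**Figure D3:**
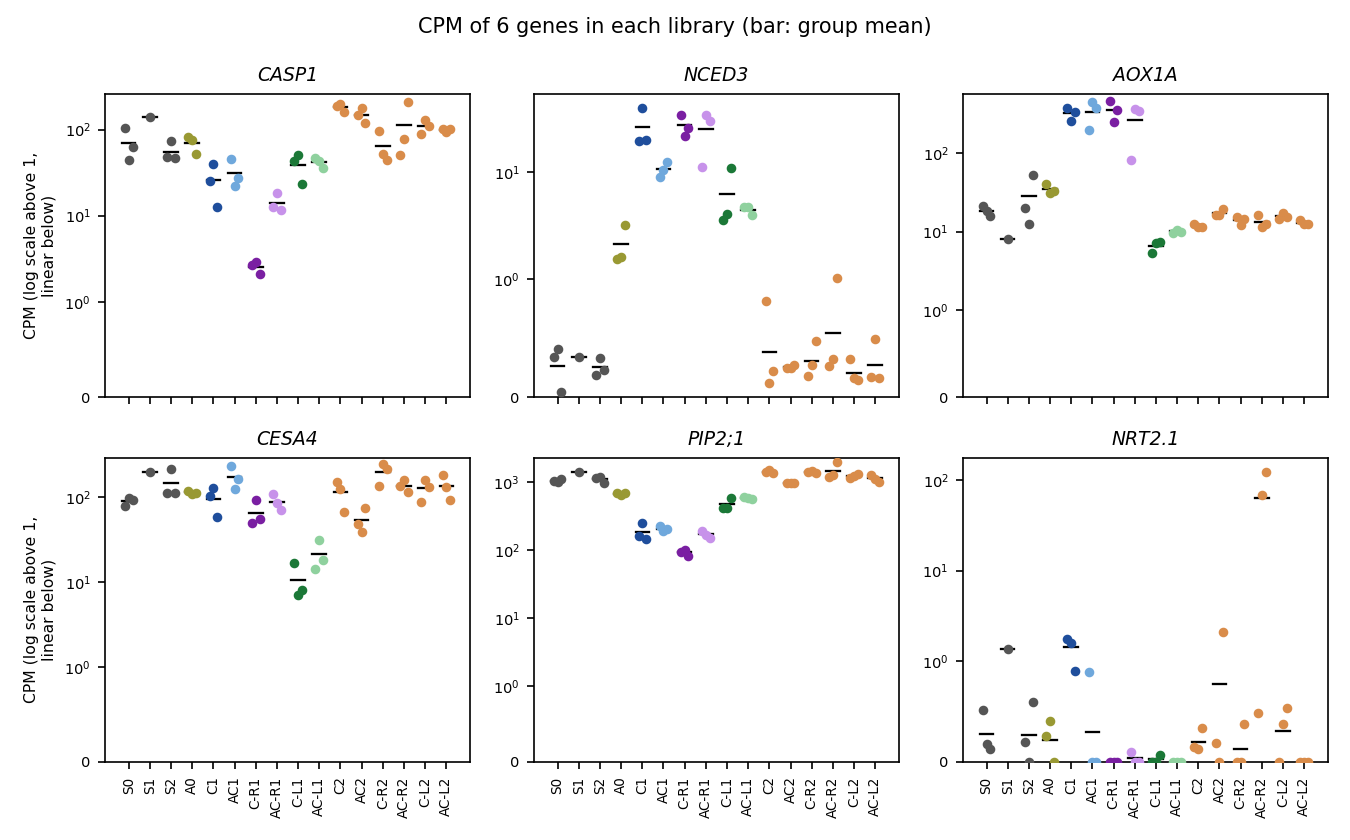
Points give the CPM of 6 genes in each library (y axis, log scale above 1 CPM and linear below) for the 16 groups on the x axis, with bars at group means. NCED3 and AOX1A stand high in the C1, AC1, C-R1 and AC-R1 groups, CESA4 low in C-L1 and AC-L1, and NRT2.1 reaches 68.8 and 122 CPM in 2 AC-R2 libraries.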

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

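Chosen only after the results were seen were the tests of library class as a term and within each class, the correlation test of an exchange of libraries and the share of genes kept with a class term in leaf cold. The acclimation difference varied with the cold target at 962 loci at 14 days, which is listed here as a difference between groups found by an interaction test. Of 100 groupings of the same 18 libraries, drawn within each cold target with the real one included, 5 gave as many loci (highest other 1994), a share of 0.05, so chance is not excluded. At 17 days the interaction called 0 loci in edgeR, and all 100 groupings gave as many (highest other 24). The 3 patterns weighed below lie in the comparisons that the interaction joins.

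In leaf cold, 1003 loci differed with acclimation, and library class followed the groups in part, since all AC-L1 and 1 of 3 C-L1 libraries were of the high class. Of these loci 77.9%, and of all tested loci 70.0%, moved in the direction of a class coefficient fitted without the AC-L1 and C-L1 libraries. Class may be a source of the pattern, in loci with and without a call. With a class term 55.7% of the 1003 were still called (559 loci). Acclimation and class cannot be told apart for the rest, because 3 against 1 libraries of the high class are left. Prior acclimation stays open as an explanation for the 559.

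In whole-plant cold, the 1520 loci of AC1 and C1 were exceeded by another split of the same 6 libraries, in which AC1 replicate 1 and C1 replicate 3, the low-class libraries, change places (4001 loci). Over the 8522 loci called in the high class, the difference between these 2 libraries correlated negatively with that of the high class (r = -0.294 across genes, which are not independent replicates), as an exchange of labels would give, and 36.1% of these loci had the same sign. On 716 loci called between AC-R1 and C-R1 in the low class, signed by direction, AC1 replicate 1 lay 0.624 log2 units above C1 replicate 3 and the high-class AC1 libraries 0.781 above theirs, which an exchange forbids. Class is held alike by AC1 and C1 (1 low and 2 high libraries each), which keeps the share of called loci that move with its coefficient (53.2%) near chance, so that this test decides nothing. What sets these 2 libraries apart, and whether acclimation acts differently in them, may be seen only with more libraries.

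AC-R1 replicate 1 lay 89.5 units from its group's median on the first principal component, towards the roots that were not cold. A mixture with RNA of such roots would need 1 cold fraction for all genes, but the median was 0.256 over 809 loci higher in cold roots and 0.890 over 451 lower ones, a difference of 0.635. Class is argued against as well, as the other 5 high-class libraries of cold roots lay at most 15.1 units from their group's median. A difference in the treatment of that sample or plant stays open and was not tested.

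For comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real count and the highest among the other splits were 3057 and 1 for A0 and S0 (1 split as large), 7435 and 2987 for C-R1 and C1 (1), 15113 and 5414 for C-L1 and C1 (1, the highest other being the split by library class), 15117 and 0 for C-L1 and C-R1 (1), 1520 and 4001 for AC1 and C1 (2), 1130 and 31 for AC-R1 and C-R1 (1), 1003 and 0 for AC-L1 and C-L1 (1), and 98 and 0 for C2 and S2 (1). They were 49 and 56 for AC-R2 and C-R2 (2, the other placing AC-R2 replicate 1 with C-R2 replicates 2 and 3). For C-R2 and C-L2 with S2, AC2 with C2 and AC-L2 with C-L2 they were 0 and 0, so that all 10 splits were as large.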

How the results depend on the processing

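Library class as a term and the fits within a class were chosen only after the results were seen, and the others were planned. Where the cause of a change is not stated below, the cause was not tested. Counts of changed loci for A0 and S0, C-R1 and S1, C-L1 and C1 and C-L1 and C-R1 stayed within 1.5 times under each alternative with all libraries. Fits of only the compared groups, which have 4 residual degrees of freedom or fewer, gave 2558 for C1 and S1, 5348 for C-L1 and S1, 1881 for C-R1 and C1, 0 for AC1 and C1, 0 for AC-R1 and C-R1, 0 for AC-L1 and C-L1, 455 for C2 and S2, 4 for C-R2 and S2 and 0 for AC-R2 and C-R2. The class term gave 2545 for AC1 and C1, 2184 for AC-R1 and C-R1, 637 for AC-L1 and C-L1, 501 for C2 and S2 and 1 for AC-R2 and C-R2. DESeq2 gave 1872 for AC-R1 and C-R1, 2236 for AC-L1 and C-L1, 5.2e+02 for C2 and S2, 67 for C-R2 and S2, 22 for C-L2 and S2, 25 for AC2 and C2, 470 for AC-R2 and C-R2, 3 for AC-L2 and C-L2, 2385 for the interaction at 14 days and 147 at 17 days. Length-scaled counts gave 1700 for AC-R1 and C-R1, 231 for C2 and S2 and 25 for AC-R2 and C-R2. DESeq2's size factors gave 65 for C2 and S2 and 4 for the interaction at 17 days, and no filter 78 for AC-R2 and C-R2 and 8 for that interaction. With 7 untreated libraries as the control the counts were 15247 for C1, 16102 for C-R1 and 13206 for C-L1. Of 304 list tests 102 passed, 7 with estimated correlations. Among lists that did not pass, the direction changed with the pooled control for gibberellin (adjusted p = 0.932) and nutrient uptake (0.775) in C1, fermentation in C-R1 (0.936) and jasmonate (0.33) and dehydrins (0.858) in C-L1.

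The replicate numbers of the labels do not pair the libraries: deviations from the group means correlated by 0.00143 on average between same-numbered libraries and by -0.000305 otherwise, 95 of 315 same-numbered pairs (30.2%) exceeded 0.1, and 16 of 45 libraries correlated best with their own number. A replicate block gave 30 for AC-R2 and C-R2 and 2 for the interaction at 17 days, and moved no other count by over 1.5 times. All 102 list tests also passed with the block, and lists without a call changed direction for nutrient uptake in C1 and S1 (adjusted p = 0.947), sugar use in AC2 and C2 (0.983) and gibberellin in AC-R2 and C-R2 (0.989).

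Leaving out each library in turn gave 1820 to 2282 loci for A0 and S0, 10962 to 11797 for C1 and S1, 11614 to 12595 for C-R1 and S1, 8178 to 9223 for C-L1 and S1, 5097 to 9039 for C-R1 and C1, 13657 to 14877 for C-L1 and C1 and 13581 to 14593 for C-L1 and C-R1. It gave 331 to 3980 for AC1 and C1, 176 to 1305 for AC-R1 and C-R1, 0 to 3305 for AC-L1 and C-L1, 0 to 170 for C2 and S2, 0 to 11 for C-R2 and S2, 0 to 7 for C-L2 and S2, 0 to 1 for AC2 and C2, 0 to 1983 for AC-R2 and C-R2 and 0 to 0 for AC-L2 and C-L2. The interaction ranged over 235 to 3716 at 14 days and 0 to 733 at 17 days. Where a group was left with 1 library, that library was assumed to vary like the other groups, and S1 could not be left out. Of the values of named genes, 12 lost their call in fits of only the compared groups, 21 with a library left out (over all libraries), 2 with the class term, 1 with DESeq2's size factors, 0 in DESeq2, 0 with the block and 0 with the pooled control. HB1 between C2 and S2 gained its call in DESeq2, with the class term and in the fit of only these groups. No called value changed direction. Differences without a call changed sign with a library left out for AOX1A (-0.0851 to 0.35) and NCED3 (-0.15 to 0.48) between C-R1 and C1, NCED3 between C2 and S2 (-0.52 to 1.03) and CESA4 between C-L2 and S2 (-0.40 to 0.18). The pooled control moved 44 of 95 fold changes of named genes against S1 by over 1.5 times, 38 of them towards 0. Depth limits genes near the floor of 3 counts, and at 3 against 1 libraries edgeR recovered 6% of simulated 2-fold changes.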

Other observations

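Single genes of ethylene synthesis, cytokinin and the clock also differed between C-L1 and S1. The ethylene (camera adjusted p = 0.343), cytokinin, clock, antioxidant and gibberellin lists did not pass there. The ethylene synthesis gene ACS2 was lower in C-L1 than in S1 (-2.44 ± 0.56, log2 ± SE), whereas it rose in C1, and the direct difference between C-L1 and C1 was -5.60 ± 0.48 (adjusted p = 1.21e-11). In the ethylene synthesis list 3 of 8 tested members fell and 5 did not pass (3 down adjusted over the list alone) between C-L1 and C1. Ethylene synthesis genes reached a camera adjusted p of 0.0338, and adjusted p = 0.292 with an estimated correlation. Cytokinin genes went both ways against S1, as 1 of 16 tested members rose, 4 fell and 11 did not pass (1 up and 4 down adjusted over the list alone), with the response regulator RR4 (-2.16 ± 0.31) and the cytokinin oxidase CKX3 (LOC_Os10g34230, -1.20 ± 0.34) falling. Cytokinin genes had a camera adjusted p of 0.402. Among clock genes 4 of 9 tested members rose, 1 fell and 4 did not pass (6 up and 2 down adjusted over the list alone), PRR95 (2.17 ± 0.43), LHY (1.01 ± 0.33) and ELF3 (1.17 ± 0.28) rising and GI (-2.29 ± 0.35) falling, while GI rose in C-R1. Clock genes gave a camera adjusted p of 0.11. Of antioxidant genes 5 of 13 tested members fell and 8 did not pass (5 down adjusted over the list alone), among them APX2 (-1.59 ± 0.30) and the catalase CATA (LOC_Os02g02400, -2.94 ± 0.85). Antioxidant genes reached a camera adjusted p of 0.136. That list passed with the 7 untreated libraries as the control (adjusted p = 0.0182). So did heat shock (adjusted p = 0.0118), where 2 of 4 tested members fell and 2 did not pass (2 down adjusted over the list alone) against S1. Heat shock genes had a camera adjusted p of 0.11. Against the 7 untreated libraries the log2 fold change was -3.28 for ACS2 and -2.25 for CATA. Gibberellin genes did not pass as a list (camera adjusted p = 0.39). Against S1, C-R1 roots had a higher potassium transporter HAK5 (LOC_Os01g70490, 3.17 ± 0.96) and phosphate signalling gene SPX1 (2.49 ± 0.41), and nutrient uptake genes did not pass as a list (camera adjusted p = 0.499).

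The test of acclimation before root cold in what follows was chosen only after the result was seen. A hypothesis was that acclimation moves transcripts of chilled roots back against the direction of cold. Of 866 loci called both between AC1 and C1 and between C-R1 and S1, which share no library, 58.1% moved in opposite directions. That is below the 75% set for it and under the bound of 60% set against it, but the upper limit of its binomial confidence interval exceeds 60%. The use of that limit was chosen only after the share was seen, and without it the share would count against the hypothesis. For root cold the share was 89.5% of 759 loci against C1 and S1, but 58.6% of 186 without AC-R1 replicate 1, so the higher share may rest on that library. AC-R1 and C-R1 hold the same class numbers, so the share of their loci moving with class (46.02%) decides nothing. The hypothesis stays undecided.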
